A study of Arabidopsis thaliana with 12 samples.

How the data were processed

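Total RNA from whole Arabidopsis seedlings was hybridized to Affymetrix ATH1 arrays, 12 in all, and each array is 1 biological replicate. The deposited value of a probe set is an intensity on the linear scale, and the submitters' processing notes name GCRMA, which corrects background and normalizes across arrays. The GCRMA version, its settings and the software that ran it are not given in the sources used here. The values were read as linear because all lie above 0 with medians of 32.7 to 35.7 per array, and they are not centred per gene. Raw array files were not used here.

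The deposited table holds 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests and read separately. Values were taken as log2 (intensity + 1), and a probe set was tested if it reached log2 4 (an intensity of 15) on at least 2 of the 12 arrays, which kept 13687 and left out 9059. A platform table of probe sets and genes, joined to RefSeq by Entrez identifier, gave 1 gene for 13513 probe sets and several genes for 503, and it does not list 8730. Of the 13513, 13436 matched RefSeq and 77 did not. Among tested probe sets 7341 had 1 gene, 1080 of them with a symbol beyond a locus number, 292 had several genes and 6054 had none assigned. Probe sets without 1 assigned gene are given by identifier. HRE1, HRE2, ADH1, PDC1, SUS4, SUS1, HB1, LBD41 and PCO1 had 0 assigned probe sets and are not analysed here.

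Arrays were grouped by genotype and oxygen from their titles, into 6 groups of 2. A single model over all 6 groups was fitted with limma (lmFit and eBayes without trend), with 6 residual degrees of freedom and 3.25 prior degrees of freedom. The 11 comparisons were hypoxia against air in each genotype, each transgenic line against WT in air and in hypoxia, the interaction of each line with hypoxia, and HRE1ox against HRE2ox in air and in hypoxia. Two-sided p-values were adjusted by Benjamini and Hochberg within a comparison, and an adjusted p under 0.05 was a call. Each SE is the moderated limma error. With 2 arrays per group, the spread is pooled over groups.

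The tests, the filter, the gene lists and the rule for naming genes were set before the data were examined. By that rule the text may name the 10 highest and 10 lowest called probe sets with a gene symbol in each hypoxia response, the 5 highest and 5 lowest in each other comparison, up to 4 called members of each list, HRE1 and HRE2, and 7 low-oxygen marker genes. Other genes and all probe sets without a gene are marked in the text as chosen after their values were seen, and genes marked once keep that status where they recur.

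From general knowledge 19 gene lists were written. They cover fermentation, glycolysis, hypoxia-responsive genes, oxygen sensing, heat shock, ethylene, reactive oxygen and calcium, pathogen defence, abscisic acid and cold, sugar starvation, expansins and xyloglucan hydrolases, flavonoids, ribosomal proteins, cell division, the clock, green tissue, roots, seed storage and reference genes. In 15 lists 1 or more members were tested, and 4 had none: pathogen defence, sugar starvation, flavonoids and seed storage. Of the 54 members of the hypoxia list 31 were assigned a probe set and 30 were tested. Each gene was read from its probe set with the highest mean. Lists of 5 or more tested genes went through limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation. This covered 4 of these lists and 32 others, which are 30 families of genes with a shared symbol and the chloroplast and mitochondrial genes. Those 32 were added after the table was seen and before any test. Camera p-values were adjusted over the 36 lists of a comparison.

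The labels give replicate numbers but do not say that equal numbers were handled together. This was checked by correlating the replicate 1 minus replicate 2 difference between groups. The 4 WT and HRE1ox groups correlated at 0.67 to 0.75 with each other and at -0.58 to -0.24 with the HRE2ox groups, which correlated at 0.35. Replicate number was therefore used as a block only in alternatives, and an 8-array fit of the WT and HRE1ox groups with that block has 3 residual degrees of freedom. The main fit thus ignores a replicate difference that the WT and HRE1ox groups shared. That difference stays in the spread, so SEs and p-values of comparisons among these groups tend to be too large. Each of these groups has 1 array of each replicate number, so the block leaves their differences unchanged and alters only the spread.

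Alternatives set in advance were a replicate block over 12 arrays, a fit on the arrays of the comparison only, centring of each array on its median, no filter, a filter at log2 6, 1 probe set per gene, eBayes with trend and robust variances, a minimum change of 2-fold, an estimated correlation in camera, and leaving out each array. Leave-one-out fits assume that the lone array left in a group varies like the other groups. They also set a group with only 1 replicate number against groups with both when a WT or HRE1ox array is left out. The replicate difference then enters the comparison, and a lost call may come from that. Added after the data were seen were the 8-array replicate block and a block with the HRE2ox replicate numbers crossed. A block for the 4 arrays whose added controls stood apart and a fit on the other 8 arrays were likewise added then. A replicate block over all 12 arrays, crossed or not, also leaves the differences unchanged.

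The fit was tested on simulated data with 200 changed probe sets, seed 17. A change of 2-fold was called for 65% of probe sets in WT hypoxia against air, 59% in HRE1ox against WT under hypoxia, 56% in HRE2ox against WT in air and 29% in the HRE1ox interaction, and a change of 4-fold for 86%, 88%, 96% and 75%. False calls numbered 11, 10, 10 and 7. The simulated noise was independent between arrays, without the replicate difference that the WT and HRE1ox groups shared. These rates may therefore not hold for the real arrays. The spread of the hypoxia list's median was taken from 10000 bootstrap draws over its genes, added after the medians were seen. The effect of shared WT arrays on 2 comparisons was simulated with 100 draws of unchanged groups. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.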

Results

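RNA from whole Arabidopsis seedlings was measured on 12 ATH1 arrays, 1 array per biological replicate. Seedlings aged 7 days were wild type (WT), or carried HRE1 or HRE2 behind the constitutive 35S promoter (HRE1ox and HRE2ox). HRE1 and HRE2 are group VII ethylene response factors, transcription factors known to act in the low-oxygen response. Each genotype spent 4 h in darkness at 23 °C in air (21% oxygen) or in hypoxia (1% oxygen), which gave 6 groups of 2 arrays. Median intensities ran from 32.7 to 35.7 across the arrays, and the small number of arrays limits the precision of every value. Differences are given on the log2 scale as mean ± SE, with n = 2 arrays in each group, and adjusted p is from limma over 13687 probe sets. A group mean under log2 4, the filter level, lies near background. A difference between such a group and one above that level is read as a lower bound in size, and an interaction that includes one is uncertain in size. In at least 1 group this holds for CML38, STZ, AT3G10040, AT5G10040, AT2G17850, AT3G29970, AT4G17670, AT4G33560, AT2G21640, AT5G51440, EXPA18, EXPA7, GH9C1, scpl28, sks15, ATC, QQS and LCR67. It also holds for several items chosen after their values were seen, among them AT5G24240, AT4G12490, AT2G07777, AT1G10585, AT2G22880, AT5G01700, AT1G47400, AT4G30680, 245173_at, 246310_at, 260869_at and 263391_at.

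HRE1 and HRE2 themselves, and the low-oxygen marker genes ADH1, PDC1, SUS4, SUS1, HB1, LBD41 and PCO1, are not analysed here, because no probe set was assigned to them. Several probe sets without an assigned gene are therefore given by their identifiers, and they were chosen after their values were seen. One label conflict concerns WT air replicate 2, whose title says wild type while its ecotype entry says 35S::HRE2. It was grouped by its title. Probe set 245173_at stood at 3.23 on that array and at 3.39 on WT air replicate 1, against a mean of 14.45 ± 0.07 (SD, n = 2) in HRE2ox air. The number of called probe sets without this array is given beside each comparison that uses it and whose number moves by over 1.5 times.

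A set of 4 arrays stood apart from the other 8 in the transcripts added before labelling. Replicate 1 of both WT groups and of both HRE1ox groups read 8.09 to 8.36 log2 for the thr 5' control, against 3.10 to 4.57 on the other arrays. The dap 5' control read 9.33 to 9.58 against 4.94 to 6.67. Their 3' probe sets differed far less. Thr 3' read 7.90 to 8.58 on the 4 arrays against 7.56 to 8.24, and dap 3' 9.27 to 9.65 against 9.73 to 10.17. What set the 4 arrays apart was thus the 5' signal of the added transcripts. The 3' minus 5' signal of the seedlings' own GAPDH was 1.88 to 2.20 on the 4 arrays and 2.41 to 2.94 on the other 8. All 4 arrays fall in WT and HRE1ox, and each of those groups has 1 of them, so they are spread evenly over WT and HRE1ox but are absent from HRE2ox. GAPDH 3' minus 5' signal averaged 2.40 ± 0.73 (SD, n = 2) in WT air, 2.29 ± 0.39 in WT hypoxia, 2.51 ± 0.44 in HRE1ox air, 2.47 ± 0.55 in HRE1ox hypoxia, 2.80 ± 0.20 in HRE2ox air and 2.55 ± 0.20 in HRE2ox hypoxia.

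**Figure D1:**
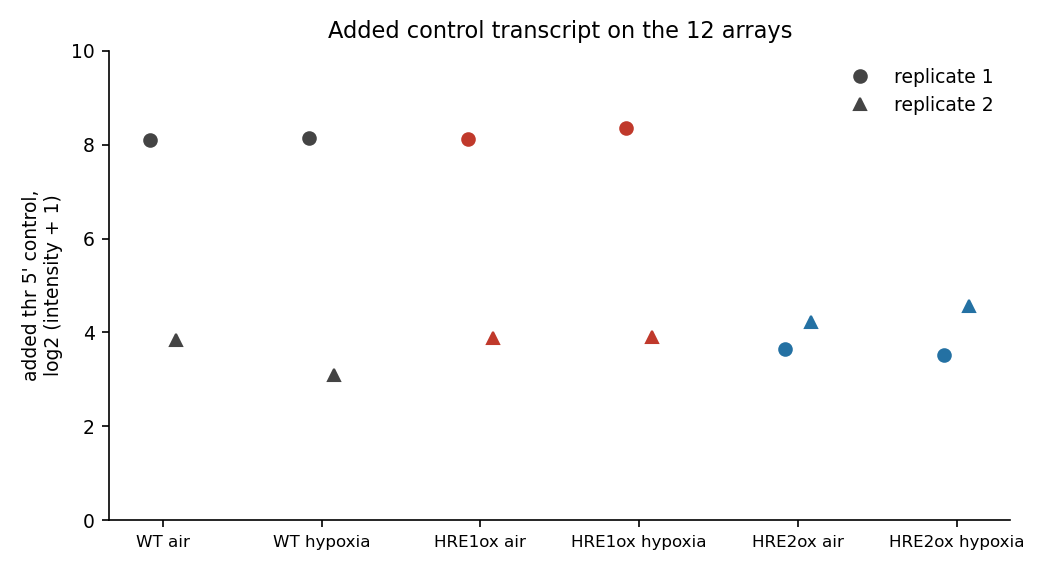
The vertical axis is the added thr 5' control transcript in log2 (intensity + 1), the horizontal axis the 6 groups, and each point 1 array, with circles for replicate 1 and triangles for replicate 2. Replicate 1 of the WT and HRE1ox groups lies between 8.09 and 8.36, and the other 8 arrays lie between 3.10 and 4.57.

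The response of wild-type seedlings to low oxygen gives the reference for both transgenic lines. PDC2, a pyruvate decarboxylase of ethanolic fermentation, rose by 4.78 ± 0.26 in WT hypoxia over WT air (adjusted p = 4.17e-06), and AT4G17260, a lactate dehydrogenase, rose by 2.61 ± 0.16 (adjusted p = 1.35e-05). CML38, a calmodulin-like protein, rose by 6.39 ± 0.20, and the zinc finger repressor STZ by 3.85 ± 0.13. AT3G10040, a trihelix transcription factor, rose by 6.00 ± 0.25. Of single genes, the root hair expansins EXPA18 and EXPA7 fell by 2.56 ± 0.38 and 1.43 ± 0.33, the endoglucanase GH9C1 fell by 2.20 ± 0.26, and the xyloglucan hydrolase XTH16 fell by 1.23 ± 0.19, while XTH18 rose by 1.41 ± 0.20 and EXPA8 by 0.81 ± 0.15. The EXPA8 call was lost without WT air replicate 2 (adjusted p = 0.0703) and without WT hypoxia replicate 1 (adjusted p = 0.0759), and the EXPA7 call without each of the 4 arrays.

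Of 30 measured hypoxia-responsive genes from the literature, 28 rose in WT hypoxia, and 28 adjusted over the list alone. Their median difference was 3.54 (camera adjusted p = 5.23e-61, and adjusted p = 7.71e-05 with an estimated correlation). AT5G10040 rose by at least 8.33 ± 0.19 and the rhodanese-like gene AT2G17850 by at least 6.95 ± 0.35, with air levels under the filter level. Both measured fermentation genes rose (2 adjusted over the list alone), and the only member measured of the oxygen-sensing list, AT3G10040, rose as well. These lists share PDC2, CML38 and AT3G10040 with the hypoxia list or with the calcium list.

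Among 5 reactive oxygen and calcium genes, CML38, STZ and AT2G21640 rose, 4 adjusted over the list alone (median 1.22, camera adjusted p = 1.88e-07, and adjusted p = 0.0199 with an estimated correlation). With an estimated correlation in the 8-array fit with the replicate block the list call was lost (adjusted p = 0.349), and the hypoxia list kept its call (adjusted p = 0.0204). The small heat shock protein AT5G51440 rose by 2.24 ± 0.35, 1 of 3 measured heat shock genes (2 adjusted over the list alone). Of 7 expansins and xyloglucan hydrolases, 2 rose and 1 fell, and the same numbers were called adjusted over the list alone (median -0.28, camera adjusted p = 0.958). Of 3 root markers, 2 fell (2 adjusted over the list alone). The ubiquitin ligases PUB23 and PUB22 rose by 1.88 ± 0.32 and 1.80 ± 0.15, and the PUB23 call was lost without WT hypoxia replicate 1 (adjusted p = 0.0561). The PUB family of 6 ligases had a median of 0.52 (camera adjusted p = 0.00116), a call lost with adjusted p = 0.093 with an estimated correlation. Chloroplast-encoded transcripts, 69 in number, had a median of 0.21 (camera adjusted p = 0.000107, and adjusted p = 0.366 with an estimated correlation), beside GAPDH 3' minus 5' values that differed between replicates. No member of the other 8 lists with measured genes passed limma's test, and 1 of their 23 members had an unadjusted p under 0.05. Those lists are glycolysis, ethylene, abscisic acid and cold, ribosomal proteins, cell division, the clock, green tissue and reference genes.

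In WT hypoxia 901 probe sets were called against WT air, 453 higher and 448 lower. The count was 620 without WT air replicate 1, 558 without WT air replicate 2, 589 without WT hypoxia replicate 1 and 581 without WT hypoxia replicate 2. Of the 29 named genes, 24 kept their call without WT air replicate 2, 24 without WT hypoxia replicate 1, 27 without WT hypoxia replicate 2 and 28 without WT air replicate 1. EXPA7 was lost in each case, with adjusted p from 0.0704 to 0.169. With replicate number as a block in the 8 WT and HRE1ox arrays, 2202 probe sets were called, among them all 901. That block leaves the differences unchanged and alters only the spread, so keeping the calls was nearly certain.

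**Figure D2:**
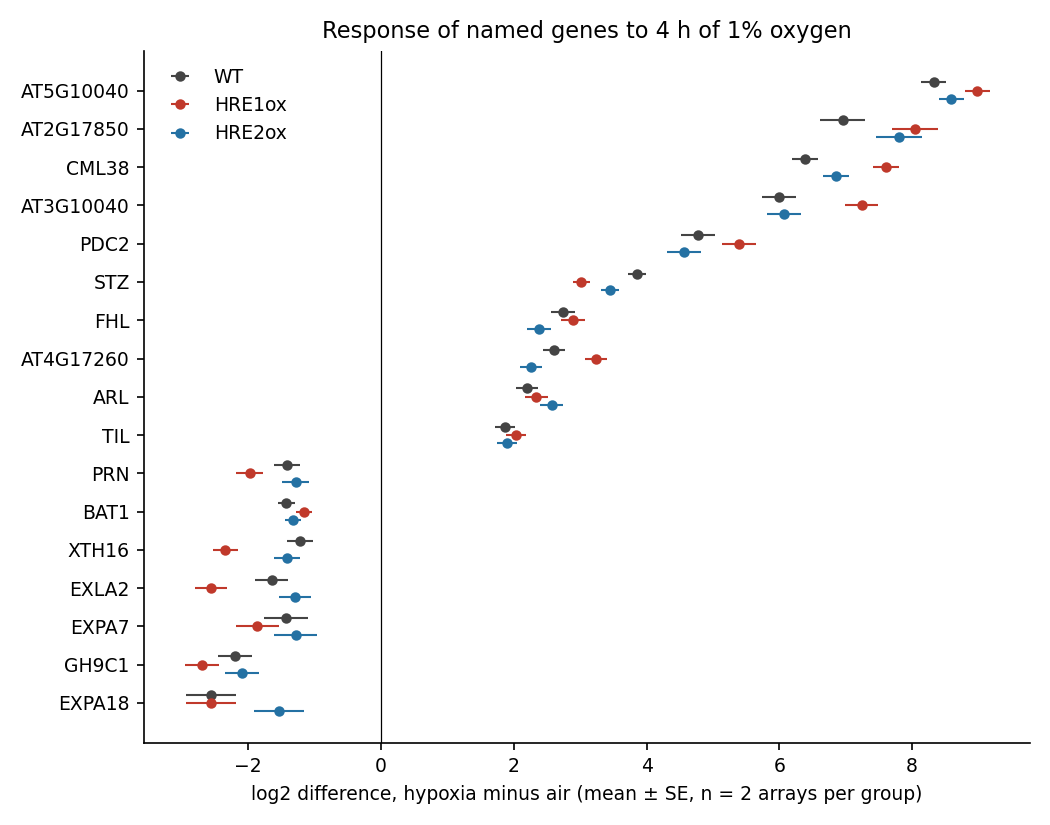
The horizontal axis is the log2 difference of hypoxia minus air, the vertical axis lists named genes, and points with bars are mean ± SE for each genotype with n = 2 arrays per group. CML38 rose by 6.39 in WT, 7.60 in HRE1ox and 6.86 in HRE2ox, while GH9C1 fell by 2.20, 2.70 and 2.09.

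HRE1ox seedlings were compared between hypoxia and air in the same way. CML38 rose by 7.60 ± 0.20, PDC2 by 5.39 ± 0.26, STZ by 3.02 ± 0.13 and AT4G17260 by 3.24 ± 0.16. FHL, which takes part in the nuclear import of phytochrome A, rose by 2.90 ± 0.18, and ARL, a promoter of organ growth, by 2.34 ± 0.17. The expansin-like genes EXLA2 and EXLA1 fell by 2.56 ± 0.25 and 1.58 ± 0.13, XTH16 fell by 2.34 ± 0.19, and EXPA18 fell by 2.56 ± 0.38. GPDHC1, a cytosolic glycerol-3-phosphate dehydrogenase, fell by 1.62 ± 0.13.

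In HRE1ox 28 of the 30 hypoxia genes rose, and 28 adjusted over the list alone, with a median of 3.88 (camera adjusted p = 4.88e-47, and adjusted p = 0.000169 with an estimated correlation). AT5G10040 rose by at least 8.98 ± 0.19 and AT2G17850 by at least 8.04 ± 0.35. Both fermentation genes rose (2 adjusted over the list alone). CML38 and STZ were the members of the reactive oxygen and calcium list that rose, 2 of 5 and 2 adjusted over the list alone (median 0.32, camera adjusted p = 0.00275). That list call was lost at adjusted p = 0.15 with an estimated correlation and at adjusted p = 0.0517 in the 8-array fit with the replicate block. Among 7 expansins and xyloglucan hydrolases 3 fell and 1 rose, with the same numbers adjusted over the list alone (median -0.37, camera adjusted p = 0.332). EXPA8, the member that rose, lost its call without HRE1ox air replicate 2 (adjusted p = 0.15) and without HRE1ox hypoxia replicate 1 (adjusted p = 0.154). No member of 8 lists passed limma's test, and 1 of their 23 members had an unadjusted p under 0.05.

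The total in HRE1ox was 1696 probe sets, 727 higher and 969 lower. It was 1093 without HRE1ox hypoxia replicate 2, and without that array 26 of the 29 named genes kept their call, among them CML38 and PDC2. AT5G51440 (1.46 ± 0.35) lost its call in each of the 4 fits without 1 array, with adjusted p of 0.12 and 0.0729 without HRE1ox air replicate 1 and replicate 2, and 0.139 and 0.0543 without HRE1ox hypoxia replicate 1 and replicate 2. With the replicate block in 8 arrays 3697 probe sets were called, among them all 1696, which that block all but ensures.

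HRE2ox seedlings were likewise compared between hypoxia and air. CML38 rose by 6.86 ± 0.20, PDC2 by 4.57 ± 0.26, STZ by 3.44 ± 0.13 and ARL by 2.57 ± 0.17. ICL, the isocitrate lyase of the glyoxylate cycle, rose by 2.49 ± 0.36, and TIL, a temperature-induced lipocalin, by 1.89 ± 0.15. GH9C1 fell by 2.09 ± 0.26, the carboxypeptidase-like gene scpl28 by 1.60 ± 0.22, XTH16 by 1.42 ± 0.19, and the acyltransferase BAT1 fell by 1.32 ± 0.12. Calls for EXPA18 at -1.53 ± 0.38 and EXPA7 at -1.28 ± 0.33 were close to the threshold (adjusted p = 0.0426 and 0.0477). Both were lost without HRE2ox air replicate 1 (0.309 and 0.32), without HRE2ox hypoxia replicate 1 (0.157 and 0.175) and without HRE2ox hypoxia replicate 2 (0.201 and 0.214).

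In HRE2ox 28 of the 30 hypoxia genes rose, and 28 adjusted over the list alone, with a median of 3.37 (camera adjusted p = 7.81e-62, and adjusted p = 7.41e-05 with an estimated correlation). AT5G10040 rose by at least 8.59 ± 0.19 and the wound-responsive family gene AT4G10270 by 8.04 ± 0.33. Both fermentation genes rose (2 adjusted over the list alone). Among 5 reactive oxygen and calcium genes CML38, STZ and AT2G21640 rose, 4 adjusted over the list alone (median 1.68, camera adjusted p = 3.09e-08, and adjusted p = 0.0152 with an estimated correlation). The small heat shock gene AT2G29500 rose by 1.16 ± 0.17, and XTH18 and EXPA8 rose by 1.23 ± 0.20 and 0.89 ± 0.15. The call was lost for XTH18 without HRE2ox air replicate 2 (adjusted p = 0.058) and without HRE2ox hypoxia replicate 1 (0.0534), and for EXPA8 without HRE2ox air replicate 2 (0.0536) and without HRE2ox hypoxia replicate 2 (0.0603). No member of 8 lists passed limma's test, and 4 of their 23 members had an unadjusted p under 0.05.

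The total in HRE2ox was 953 probe sets, 463 higher and 490 lower. It was 485 without HRE2ox air replicate 1, 541 without HRE2ox air replicate 2, 584 without HRE2ox hypoxia replicate 1 and 472 without HRE2ox hypoxia replicate 2. With the 4 arrays apart as a block 1945 were called, and with a replicate block whose numbers were crossed in HRE2ox (the crossed replicate block) 1974, each time with all 953 among them, in alternatives chosen after the data were seen. Of the 30 named genes, 24 kept their call without either HRE2ox air array and 22 without either HRE2ox hypoxia array, and 20, CML38, PDC2 and GH9C1 among them, kept it in all 4 fits. EXLA2 (-1.30 ± 0.25) and PUB23 (1.54 ± 0.32) lost theirs in each, with adjusted p of 0.106 and 0.154 without HRE2ox air replicate 1, 0.061 and 0.0763 without HRE2ox air replicate 2, 0.0674 and 0.0915 without HRE2ox hypoxia replicate 1, and 0.0898 and 0.126 without HRE2ox hypoxia replicate 2.

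The 3 hypoxia responses were set against each other probe set by probe set. CML38, PDC2, STZ, FHL, ARL, TIL and AT4G17260 were called higher in all 3 genotypes, and GH9C1, EXPA18, EXPA7, EXLA2, XTH16 and BAT1 lower in all 3. In all, 300 probe sets were called higher and 293 lower in every genotype, out of 2003 called in at least 1, and 2 were called in opposite directions. WT shared 359 higher and 387 lower with HRE1ox, where independent lists would share 24.1 and 31.7. WT shared 333 higher and 312 lower with HRE2ox, where 15.3 and 16 were expected. HRE1ox and HRE2ox shared 349 higher and 398 lower, where 24.6 and 34.7 were expected. Each genotype has its own air arrays, so no control array was shared in these overlaps. The spread of a probe set was pooled over all 12 arrays, however, so the lists are not fully independent and the expected numbers may be too low. Across probe sets, which are not independent replicates, the responses correlated at Pearson r = 0.862 for WT with HRE1ox, 0.867 for WT with HRE2ox and 0.82 for HRE1ox with HRE2ox (Spearman rho 0.684, 0.67 and 0.607).

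**Figure D3:**
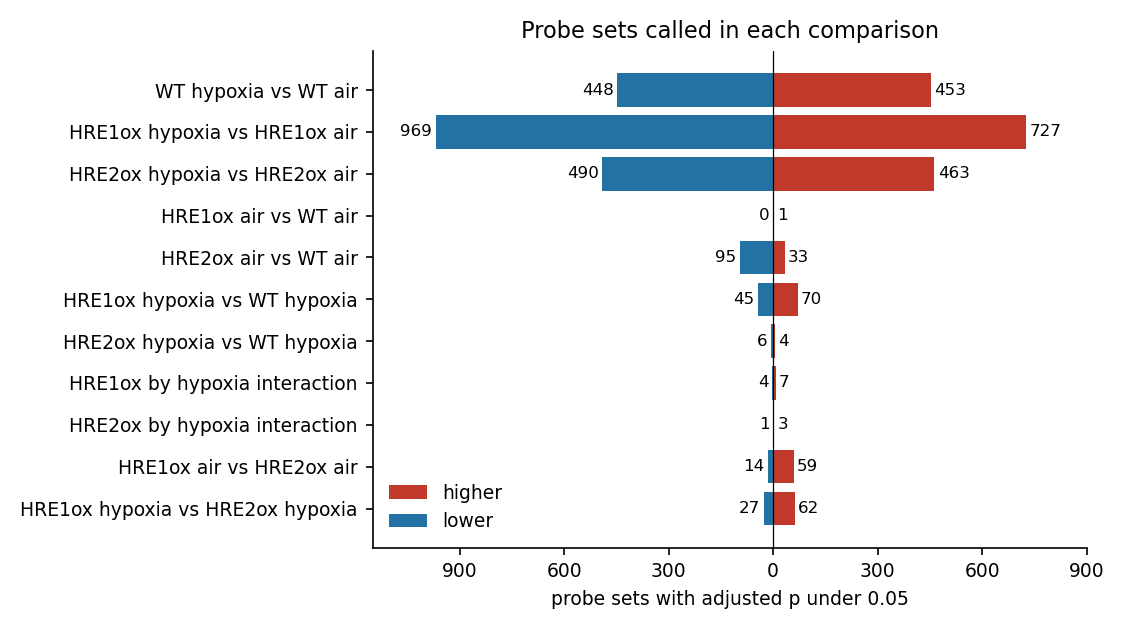
Bars give the number of probe sets called by limma at adjusted p under 0.05, with higher to the right and lower to the left of 0, for each of the 11 comparisons. The 3 hypoxia responses hold 901, 1696 and 953 calls, and comparisons between genotypes hold 1 to 128.

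HRE1ox was compared with WT in air to find what the HRE1 transgene changed before low oxygen. Probe set 260451_at, with no assigned gene, rose by 8.01 ± 0.20 (adjusted p = 1.46e-07), from 6.18 ± 0.30 (SD, n = 2) in WT air to 14.19 ± 0.04 in HRE1ox air. CML38, PDC2 and STZ were among the genes not called here. Of the 30 hypoxia genes 0 were called by limma, 5 had an unadjusted p under 0.05, and 1 was lower adjusted over the list alone. The list had a median of 0.03, a mean of -0.001 and a camera direction of down, and its test was not passed (camera adjusted p = 0.941). That median turned negative without either WT air array and with the 8 like arrays alone. The ATG family of 8 autophagy genes had a median of 0.39 (camera adjusted p = 0.0242, and adjusted p = 0.463 with an estimated correlation), and its call was lost without HRE1ox air replicate 2 (adjusted p = 0.182) and without WT air replicate 1 (adjusted p = 0.153).

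260451_at was the only call in HRE1ox air, while 1338 probe sets had an unadjusted p under 0.05. A second probe set was called without HRE1ox air replicate 1, which made 2, and centring each array on its median gave 7 calls, 85.7% of them higher against 100% before. With replicate number as a block in the 8 WT and HRE1ox arrays 185 probe sets were called, 109 higher and 76 lower, an alternative chosen after the data were seen. In that fit the cysteine protease CP1 was higher by 1.43 ± 0.16, ICL by 1.23 ± 0.14 and FHL by 1.07 ± 0.14, and the SKU5-like gene sks15 was lower by 1.58 ± 0.25 and the glycosyltransferase UGT73B4 by 0.98 ± 0.13.

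HRE2ox was compared with WT in air for the effect of the HRE2 transgene. AT4G10270, AT4G33560 and AT5G66985, 3 members of the hypoxia list, fell by 1.86 ± 0.33, 1.78 ± 0.20 and 1.30 ± 0.12 (adjusted p = 0.0388, 0.00611 and 0.00163). Among genes with other roles, sks15 fell by 1.90 ± 0.29, ATC, a relative of flowering repressors, by 1.68 ± 0.29, the pectin methylesterase ATPMEPCRB by 1.07 ± 0.20, the glucosinolate transporter GTR2 by 0.87 ± 0.14 and the stromal ascorbate peroxidase SAPX by 0.82 ± 0.15. QQS, a gene that affects starch content, rose by 1.11 ± 0.19, and the glutathione transferase GSTU18 rose by 0.71 ± 0.13. Chosen after their values were seen, 245173_at rose by 11.14 ± 0.20 and AT5G24240 by 4.75 ± 0.15, and AT4G12490 fell by 3.28 ± 0.32 and AT2G04050 by 2.99 ± 0.32.

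Of the 30 hypoxia genes 3 fell and 0 rose in HRE2ox air, and 4 fell adjusted over the list alone. The list median was -0.03, and it was more negative in each fit without 1 array. The list was called (camera adjusted p = 0.0409), a call lost at adjusted p = 0.297 with an estimated correlation. It was lost as well without HRE2ox air replicate 2 (median -0.05, camera adjusted p = 0.0765) and without WT air replicate 1 (median -0.09, camera adjusted p = 0.144). Expansins and xyloglucan hydrolases had a median of -0.54 (camera adjusted p = 0.0158), ribosomal proteins -0.26 (0.0178) and reactive oxygen and calcium genes -0.50 (0.0174), and each was lost at adjusted p = 0.297 with an estimated correlation. These calls were lost for the expansins without WT air replicate 1 (0.124), for the ribosomal proteins without HRE2ox air replicate 1 (0.129) and without WT air replicate 2 (0.156), and for the calcium list without HRE2ox air replicate 2 (0.0539). Chloroplast-encoded transcripts had a median of 0.27 (camera adjusted p = 0.000539, adjusted p = 0.3 with an estimated correlation, and 0.0743 without HRE2ox air replicate 2), beside a GAPDH 3' minus 5' signal of 2.80 ± 0.20 in HRE2ox air and 2.40 ± 0.73 in WT air. By limma, 0 members of 14 lists were called, and 11 of their 44 members had an unadjusted p under 0.05.

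HRE2ox air gave 128 calls against WT air, 33 higher and 95 lower. The number was 18 without HRE2ox air replicate 1, 22 without HRE2ox air replicate 2, 19 without WT air replicate 1 and 42 without WT air replicate 2, the array with conflicting labels. Without that array 36 of the 128 remained called, and all 128 kept their direction. Among the 10 named genes AT5G66985 kept its call in all 4 such fits, and 7 to 9 of the others lost theirs: 8 without either HRE2ox air array, 9 without WT air replicate 1 and 7 without WT air replicate 2. Using only the 8 arrays with like added controls 6 were called, and with the 4 arrays apart as a block 799 were called, among them all 128.

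HRE1ox was compared with WT under hypoxia for the effect of the HRE1 transgene at low oxygen. Of the 30 hypoxia genes 29 were higher in HRE1ox, with a median of 0.42 (camera adjusted p = 2.29e-12, and adjusted p = 0.00809 with an estimated correlation). In the 8-array fit with the replicate block the list passed at camera adjusted p = 8.03e-11, a call lost at adjusted p = 0.154 with an estimated correlation. The list members that passed on their own were AT3G29970 at 1.74 ± 0.31 (adjusted p = 0.0434) and AT4G17670 at 0.83 ± 0.14 (adjusted p = 0.0364), 2 over all probe sets and 13 adjusted over the list alone. FHL rose by 1.22 ± 0.18, the cysteine-rich peptide gene LCR67 by 1.15 ± 0.13, the glycosyltransferase UGT85A4 by 0.97 ± 0.16 and AILP1 by 0.87 ± 0.13. STZ fell by 1.01 ± 0.13, and the chloroplast-encoded petN, petD and rpl20 fell by 1.47 ± 0.26, 1.31 ± 0.24 and 1.13 ± 0.15. PetN and petD belong to the cytochrome b6f complex and rpl20 to the chloroplast ribosome.

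Expansins and xyloglucan hydrolases were lower with a median of -0.34 (camera adjusted p = 0.00502), a call lost at adjusted p = 0.361 with an estimated correlation and at 0.197 without HRE1ox hypoxia replicate 2, and 0 members were called by limma, 2 with an unadjusted p under 0.05 and 1 adjusted over the list alone. STZ was the only member of the reactive oxygen and calcium list called, and 1 member was higher and 3 lower adjusted over the list alone (median -0.97, camera adjusted p = 0.0673). Chloroplast-encoded transcripts had a median of -0.21 over 69 genes (camera adjusted p = 1.3e-08, and adjusted p = 0.305 with an estimated correlation). GAPDH 3' minus 5' signal was 2.47 ± 0.55 (SD, n = 2) in HRE1ox hypoxia and 2.29 ± 0.39 in WT hypoxia. Of the 70 probe sets higher in HRE1ox, 36 were hypoxia-induced in HRE2ox, where 2.4 were expected for independent lists. Of the 45 lower, 16 were hypoxia-induced in HRE2ox, where 1.5 were expected, and 9 were hypoxia-repressed, where 1.6 were expected. The groups compared share no array, but the spread of a probe set was pooled over all 12 arrays. Probe sets with a small spread are then called more readily in both lists, so the expected numbers may be too low.

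HRE1ox hypoxia gave 115 calls against WT hypoxia, 70 higher and 45 lower. The number was 39 without WT hypoxia replicate 1, 31 without WT hypoxia replicate 2, 37 without HRE1ox hypoxia replicate 1 and 29 without HRE1ox hypoxia replicate 2. Of the 10 named genes, 2 kept their call without WT hypoxia replicate 1, 3 without WT hypoxia replicate 2, 2 without HRE1ox hypoxia replicate 1 and 1 without HRE1ox hypoxia replicate 2, and none of them, FHL and LCR67 included, did in all 4 fits. In the 8-array fit with the replicate block 469 were called, among them all 115, which that block all but ensures. There 8 of the 30 hypoxia genes were called. Using only the 8 arrays with like added controls 0 probe sets were called by limma, and all 115 kept their direction.

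**Figure D4:**
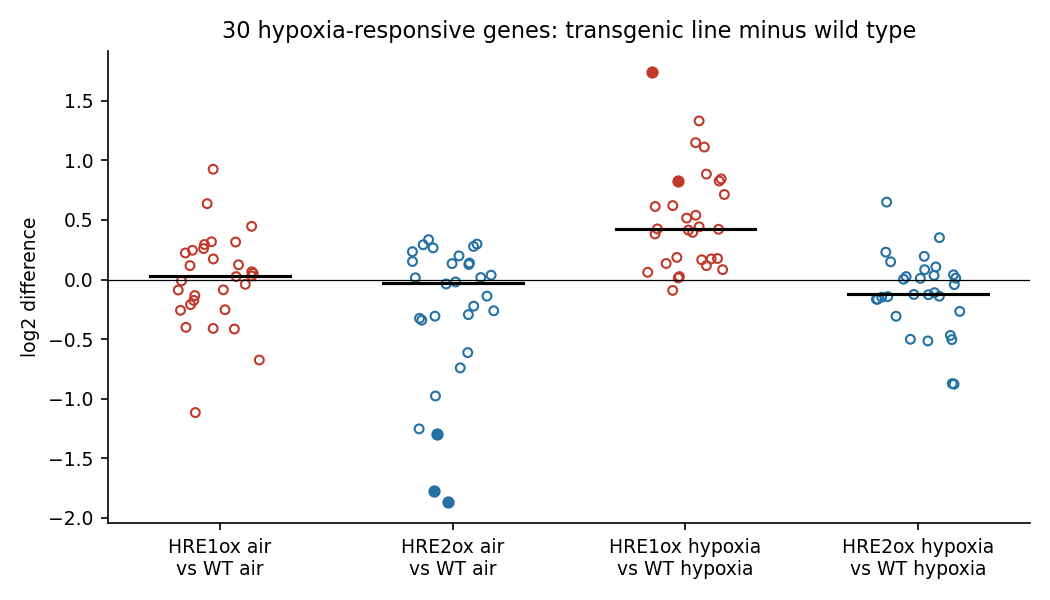
The vertical axis is the log2 difference of a transgenic line from WT, and each point is 1 of 30 hypoxia-responsive genes in 4 comparisons, with filled points called by limma and lines at the median. Medians were 0.03 and -0.03 in air for HRE1ox and HRE2ox, and 0.42 and -0.12 under hypoxia.

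HRE2ox was compared with WT under hypoxia likewise, and all 10 calls are given, chosen after their values were seen. Higher were 245173_at by 4.98 ± 0.20, AT5G24240 by 4.35 ± 0.15, 259789_at by 1.47 ± 0.16 and AT1G66100 by 1.03 ± 0.13. Lower were 266165_at by 1.99 ± 0.21, AT2G07777 by 1.94 ± 0.18, AT1G10585 by 1.29 ± 0.12, 245306_at by 1.00 ± 0.13, AT1G73600 by 0.99 ± 0.13 and 248048_at by 0.99 ± 0.12. Of the 30 hypoxia genes 0 were called by limma, 5 had an unadjusted p under 0.05 and 0 were called adjusted over the list alone, and the list median of -0.12 did not pass (camera adjusted p = 0.296). Without a filter on dim probe sets that list passed, with a median of -0.11 and camera adjusted p = 0.0204.

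The 10 calls in HRE2ox hypoxia stood beside 1238 probe sets with an unadjusted p under 0.05. The number was 3 without HRE2ox hypoxia replicate 1, 2 without HRE2ox hypoxia replicate 2, 3 without WT hypoxia replicate 1 and 6 without WT hypoxia replicate 2. With the 4 arrays apart as a block 101 were called and with the crossed replicate block 147, each time with all 10 among them, and with the 8 like arrays alone 2. Of the 10, 3 higher and 4 lower were called in the same direction in HRE2ox air, with 0 expected for independent lists. HRE1ox and HRE2ox shared 5 calls against WT under hypoxia, which were 259789_at and AT1G66100 higher and 266165_at, AT1G10585 and 245306_at lower. Both comparisons use the same WT hypoxia arrays, so part of the excess may come from shared controls. Independent lists would share 0. The 100 simulated draws of unchanged groups shared at most 0, but groups without change leave few calls to share, so they cannot weigh this. In air, with other WT arrays, 259789_at and AT1G66100 were also higher in both lines, and 266165_at and 245306_at lower. AT1G10585 lay near background in air in every genotype. Across probe sets the 2 differences from WT correlated at r = 0.464 under hypoxia, where simulated unchanged groups gave 0.501, with a covariance of 0.0349 beside a simulated 0.0351. The simulation drew independent noise for each array. It leaves out the replicate difference that WT and HRE1ox shared and HRE2ox did not. In air r was 0.43 against 0.5 in simulation, the covariance 0.041 beside 0.0349, and 0 calls were shared, with 1 and 128 calls by limma and 1338 and 2082 probe sets at an unadjusted p under 0.05.

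Whether the hypoxia response itself differed from WT was tested by the interaction. In HRE1ox the 30 hypoxia genes had a median interaction of 0.54, positive in 24 (camera adjusted p = 5.89e-09, and adjusted p = 0.0194 with an estimated correlation). In the 8-array fit with the replicate block the list passed at camera adjusted p = 8.76e-07, a call lost at adjusted p = 0.286 with an estimated correlation. None was called over all probe sets by limma, 9 had an unadjusted p under 0.05, and 7 were higher adjusted over the list alone. The XTH family of 5 xyloglucan hydrolases had a median of -0.80 (camera adjusted p = 7.81e-05), lost at adjusted p = 0.0606 with an estimated correlation. Chosen after their values were seen, probe set 263391_at (1.90 ± 0.19), AT2G22880, a VQ-motif gene (1.56 ± 0.21), and AT5G01700 (1.42 ± 0.19) had positive interactions, and AT1G47400 (-1.99 ± 0.24), AT5G45950 (-1.67 ± 0.21) and 260451_at (-4.26 ± 0.28) had negative ones.

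The interaction gave 11 calls in HRE1ox, 7 higher and 4 lower, with 762 probe sets at an unadjusted p under 0.05. The number was 3 without HRE1ox air replicate 1, 1 without HRE1ox air replicate 2, 1 without WT air replicate 1, 1 without WT air replicate 2, 1 without WT hypoxia replicate 1, 1 without WT hypoxia replicate 2, 6 without HRE1ox hypoxia replicate 1 and 3 without HRE1ox hypoxia replicate 2. Centring each array on its median left 2 calls, 50% of them higher against 63.6% before. In the 8-array fit with the replicate block 79 probe sets were called, among them all 11, and using only the 8 arrays with like added controls 0 were called by limma.

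In HRE2ox the interaction was called for 4 probe sets without an assigned gene, chosen after their values were seen. Probe sets 260869_at, 263096_at and 264953_at rose more in HRE2ox than in WT, by 2.77 ± 0.27, 2.66 ± 0.30 and 1.99 ± 0.21, and 245173_at had an interaction of -6.16 ± 0.28. In air 264953_at stood at 7.42 ± 0.02 (SD, n = 2) in HRE2ox and 9.58 ± 0.25 in WT, and in hypoxia at 14.06 ± 0.00 and 14.22 ± 0.09. The 30 hypoxia genes had a median interaction of 0.02 (camera adjusted p = 0.324), with 0 called by limma, 5 at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. The 4 calls stood beside 354 probe sets at an unadjusted p under 0.05. The number was 2 without HRE2ox air replicate 1, 2 without HRE2ox air replicate 2, 1 without HRE2ox hypoxia replicate 1, 1 without HRE2ox hypoxia replicate 2, 1 without WT air replicate 1, 2 without WT hypoxia replicate 1, 2 without WT hypoxia replicate 2 and 4 without WT air replicate 2. It was 17 with the 4 arrays apart as a block, 8 with the crossed replicate block and 1 with the 8 like arrays alone.

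**Figure D5:**
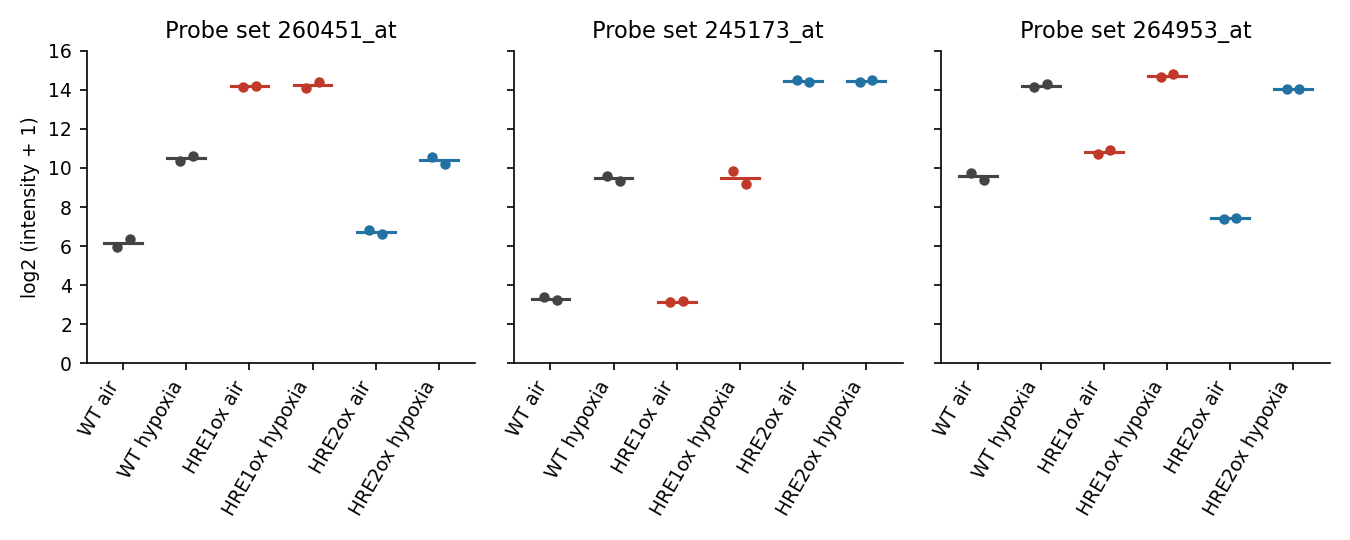
The vertical axis is log2 (intensity + 1) and the horizontal axis the 6 groups for probe sets 260451_at, 245173_at and 264953_at, with each point 1 array and lines at group means. 260451_at stood at 14.19 and 14.25 in HRE1ox air and hypoxia, and 245173_at at 14.45 and 14.46 in HRE2ox air and hypoxia.

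The transgenic lines were compared directly with each other, first in air. ICL was higher in HRE1ox than in HRE2ox by 2.26 ± 0.36, ATPMEPCRB by 1.33 ± 0.20 and XTH19 by 0.97 ± 0.14, and QQS was lower by 1.19 ± 0.19. AT3G29970 and AT5G66985 of the hypoxia list were higher by 2.18 ± 0.31 and 0.90 ± 0.12, which made 2 of 30 called and 3 adjusted over the list alone. The list median was 0.10 (camera adjusted p = 0.0196), lost at adjusted p = 0.179 with an estimated correlation, at 0.0569 without HRE1ox air replicate 1 and at 0.0583 without HRE2ox air replicate 2. Expansins and xyloglucan hydrolases had a median of 0.68 (camera adjusted p = 0.000618), lost at adjusted p = 0.179 with an estimated correlation, and XTH19 was the member called, with 4 adjusted over the list alone. In all 73 probe sets were called, 59 higher and 14 lower in HRE1ox. The number was 37 without HRE1ox air replicate 1, 18 without HRE1ox air replicate 2, 18 without HRE2ox air replicate 1 and 23 without HRE2ox air replicate 2, and 2, 0, 0 and 1 of the 6 named genes kept their call. The arrays with a high 5' signal of the added controls are in HRE1ox and not in HRE2ox. Using only the 8 like arrays, a fit with 1 HRE1ox air array, all 73 kept their direction. Called probe sets did so in every alternative, so their direction cannot weigh the labelling. With the 4 arrays apart as a block 427 were called and with the crossed replicate block 658, each time with all 73 among them.

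Under hypoxia 29 of the 30 hypoxia genes were higher in HRE1ox than in HRE2ox, with a median of 0.68 (camera adjusted p = 7.65e-17, and adjusted p = 0.0034 with an estimated correlation). AT4G17670 and AT5G66985 were called, at 0.81 ± 0.14 and 0.72 ± 0.12, and 15 were called adjusted over the list alone. The lactate dehydrogenase AT4G17260 was higher by 1.42 ± 0.16, FHL by 1.22 ± 0.18, LCR67 by 1.20 ± 0.13, the peroxidase Prx37 by 1.00 ± 0.17, UGT85A4 by 0.91 ± 0.16 and AILP1 by 0.83 ± 0.13. QQS was lower by 1.48 ± 0.19. In all 89 probe sets were called, 62 higher and 27 lower in HRE1ox. The number was 30 without HRE2ox hypoxia replicate 1, 28 without HRE2ox hypoxia replicate 2, 33 without HRE1ox hypoxia replicate 1 and 31 without HRE1ox hypoxia replicate 2. LCR67 kept its call in all 4 fits, and of the 9 named genes 2 kept theirs without HRE2ox hypoxia replicate 1, 2 without HRE2ox hypoxia replicate 2, 2 without HRE1ox hypoxia replicate 1 and 1 without HRE1ox hypoxia replicate 2. Using only the 8 arrays with like added controls 4 were called. With the 4 arrays apart as a block 353 were called and with the crossed replicate block 318, each time with all 89 among them.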

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

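Of the tests in this part, the labelling block and the level of 245173_at in the array with conflicting labels were chosen only after the result was seen, as was the spread of the list medians. The replicate-pair test and the matched-list test were set before their results.

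The hypoxia response differed between HRE1ox and WT by a test of the interaction in limma for 11 probe sets. All are given, chosen after their values were seen. Higher were 263391_at by 1.90, 253404_at by 1.65, AT2G22880 by 1.56, AT4G30680 by 1.52, 246310_at by 1.46, 264561_at by 1.44 and AT5G01700 by 1.42. Lower were AT1G10585 at -1.25, AT5G45950 at -1.67, AT1G47400 at -1.99 and 260451_at at -4.26. Of these, 263391_at, AT2G22880, AT4G30680, 246310_at, AT5G01700, AT1G10585 and AT1G47400 had a mean under log2 4, near background, in at least 1 of the 4 groups, so their sizes are uncertain. Without 1 array the number was 3 (HRE1ox air replicate 1), 1 (HRE1ox air replicate 2), 6 (HRE1ox hypoxia replicate 1), 3 (HRE1ox hypoxia replicate 2) or 1 (each of the 4 WT arrays). The 30 hypoxia genes had a median interaction of 0.54 and passed as a list, a call lost in the 8-array blocked fit with an estimated correlation (adjusted p = 0.286).

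In HRE2ox the interaction was called for 4 probe sets without an assigned gene, likewise chosen after their values were seen, 260869_at at 2.77, 263096_at at 2.66, 264953_at at 1.99 and 245173_at at -6.16. The first 3 stood lower in HRE2ox than in WT in air, at 2.53 against 5.55, 7.22 against 9.78 and 7.42 against 9.58 (means, n = 2), and in hypoxia at 10.05 against 10.29, 13.21 against 13.11 and 14.06 against 14.22. Without HRE2ox hypoxia replicate 1, HRE2ox hypoxia replicate 2 or WT air replicate 1 the number was 1, and without HRE2ox air replicate 1, HRE2ox air replicate 2, WT hypoxia replicate 1 or WT hypoxia replicate 2 it was 2.

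The first pattern weighed is the higher level of hypoxia genes in HRE1ox than in WT under hypoxia, such as AT3G29970 and AT4G17670. The difference between replicate 1 and replicate 2 arrays is argued against as its whole cause. Each of the 2 groups has 1 array of each replicate number, so a difference common to both groups cancels. The list median was 0.47 between the replicate 1 arrays and 0.39 between the replicate 2 arrays. The middle 95% of bootstrap draws ran from 0.24 to 0.73 and from 0.26 to 0.54. These draws were over genes and do not measure the spread between arrays. A stronger low-oxygen exposure of the HRE1ox arrays cannot be told apart. The list's median interaction of 0.54 was at percentile 98.9 of 10000 lists of 30 probe sets matched on their response in HRE2ox. It lay above their middle 95%, from -0.11 to 0.45, which by the rule set before counts against exposure. The matched lists had a median interaction of 0.16 and a smaller response in HRE2ox, 3.13 against 3.37. The spread of the hypoxia list's median over genes (0.24 to 0.75), added after the medians were seen, reached into that range, but such an overlap is no test. Both ranges come from draws over genes and do not measure the spread between arrays, so the question stays open. Other probe sets did not settle it: the 490 repressed in HRE2ox had a median interaction of -0.226 (camera p = 0.00843 with an estimated correlation, 0.0169 in the 8-array blocked fit) and the 463 induced 0.122 (0.0199 and 0.0594), as a larger response would need, but in HRE1ox against WT the repressed ones differed by -0.079 under hypoxia (0.0885 and 0.102) and by 0.119 in air (0.0507 and 0.0456), where low oxygen was not applied, and the induced ones by 0.099 under hypoxia (0.0155 and 0.0511). Calls in HRE1ox against WT under hypoxia went both ways. Of the 70 higher, 36 were hypoxia-induced in HRE2ox and 2 repressed. Of the 45 lower, 9 were repressed and 16 induced, and a uniformly larger response would not lower those 16. An effect of the HRE1 transgene on the hypoxia genes stays open as a hypothesis. It is limited by the 8-array blocked fit, where the list interaction had camera adjusted p = 0.286 with an estimated correlation.

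The second pattern weighed is the set of transcripts lower in HRE2ox than in WT in air, which includes AT4G10270, AT4G33560 and AT5G66985. Unequal labelling of the arrays cannot be told apart as a cause. All 128 called probe sets kept call and direction with the 4 arrays apart as a block. So did the calls of all 11 comparisons, so keeping them does not weigh labelling. In comparisons among WT and HRE1ox groups, each with 1 of the 4 arrays, the block leaves the differences unchanged. The block also sets the HRE2ox air arrays level with WT replicate 2. On a scale from 0 at WT replicate 2 to 1 at WT replicate 1, they stood at 0.15 and 0.34. Among the 8 like arrays alone 6 were called, in a fit with 1 WT air array. A mislabelled WT air replicate 2 is argued against by 245173_at, which differed by 0.16 between the WT air arrays while it was 11.14 higher in HRE2ox air than in WT air. An effect of the HRE2 transgene may explain these transcripts, and a difference between seed lots or plates was not tested.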

How the results depend on the processing

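The fits with an 8-array replicate block, a crossed block, a block for the 4 arrays apart and the 8 like arrays alone were tests chosen only after the data were seen; the others were set before. No called value reversed its direction. Of gene differences 1143 kept their side of the threshold and 130 were weaker, and without 1 array 325 kept it and 167 were weaker. Of list tests 732 kept it, 9 were stronger and 101 weaker, and without 1 array 287, 4 and 61. Of counts 58 stayed within 1.5 times and 77 moved, and without 1 array 8 and 44. Where no reason is given, the cause was not tested.

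A minimum change of 2-fold left 561 calls in WT hypoxia, 895 in HRE1ox hypoxia, 551 in HRE2ox hypoxia, 64 in HRE2ox against WT in air and 56 between the lines under hypoxia, fewer by construction. With 1 probe set per gene fewer were tested, and the counts were 416, 806 and 420 for the responses of WT, HRE1ox and HRE2ox. They were 0 and 35 for HRE1ox and HRE2ox against WT in air, 51 and 5 under hypoxia, 6 and 0 for the interactions, and 32 and 39 between the lines in air and hypoxia. The calls alike in all 3 genotypes were then 261. Where limma gave 0 calls in this part, the 12-array fit had 1338 (HRE1ox air), 1085 (HRE1ox against WT under hypoxia), 762 (HRE1ox interaction) and 354 (HRE2ox interaction) probe sets at unadjusted p under 0.05.

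A fit on the arrays of the comparison only has fewer degrees of freedom, and gave 366 in WT hypoxia and 755 in HRE1ox hypoxia. It gave 7 in HRE2ox air, 0 and 2 for HRE1ox and HRE2ox against WT under hypoxia, 1 and 1 for the interactions, and 10 and 4 between the lines. The replicate block over 12 arrays gave 2 calls in HRE1ox air and 17 in HRE2ox hypoxia against WT, and it changed no other count by over 1.5 times. Median-centring gave 7 in HRE1ox air and 2 in the HRE1ox interaction. No filter gave 20 in HRE1ox air, 254 in HRE2ox air, 19 in HRE2ox hypoxia against WT and 115 between the lines in air. The filter at log2 6 gave 5 in HRE1ox air and 1 in the HRE1ox interaction, and eBayes with trend and robust variances gave 3 and 1.

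The 8-array replicate block gave 2202 in WT hypoxia, 3697 in HRE1ox hypoxia, 185 in HRE1ox air, 469 in HRE1ox hypoxia against WT and 79 in the interaction. All 901, 1696, 1, 115 and 11 calls were among them. That block left the differences unchanged, so keeping the calls was nearly certain. The block for the 4 arrays apart gave 1862, 3194 and 1945 for the responses, 141 and 799 against WT in air, 382 and 101 under hypoxia, 82 and 17 for the interactions, 427 and 353 between the lines, and 1123 alike in all genotypes, with the earlier calls kept in direction. The 8 like arrays alone gave 410 and 904 in WT and HRE1ox hypoxia, 6 in HRE2ox air, 0 and 2 against WT under hypoxia, 0 and 1 for the interactions, 12 and 4 between the lines, and 327 alike, with 1 array in each WT and HRE1ox group. The crossed block gave 1767, 3052, 1974, 157, 1100, 353, 147, 64, 8, 658, 318 and 1085 in the same order.

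Leaving out 1 array gave 558 to 620 calls in WT hypoxia, 1093 to 1221 in HRE1ox hypoxia and 472 to 584 in HRE2ox hypoxia. It gave 1 to 2 in HRE1ox air, 18 to 42 in HRE2ox air, 29 to 39 in HRE1ox and 2 to 6 in HRE2ox against WT under hypoxia, 1 to 6 and 1 to 4 for the interactions, and 18 to 37 and 28 to 33 between the lines in air and hypoxia.

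The hypoxia list in HRE2ox against WT in air had a median of -0.028 and camera adjusted p = 0.0409. It was no longer called with an estimated correlation (median -0.028, adjusted p = 0.297), the 12-array block (-0.028, 0.0579), no filter (-0.020, 0.082), the crossed block (-0.028, 0.101), the block for the 4 arrays (-0.016, 0.274) or the 8 like arrays (-0.094, 0.207). Without 1 array the median ran from -0.258 to -0.045, and the call was lost without HRE2ox air replicate 2 (0.0765) and WT air replicate 1 (0.144). Between the lines in air it had a median of 0.10 and adjusted p = 0.0196. It was lost with an estimated correlation (0.10, 0.179), no filter (0.083, 0.068), the block for the 4 arrays (0.066, 0.126) and the 8 like arrays (0.062, 0.0877). Without 1 array the median ran from 0.062 to 0.263, and the call was lost without HRE1ox air replicate 1 (0.0569) and HRE2ox air replicate 2 (0.0583). In HRE1ox against WT in air the list was not called (median 0.028, camera direction down). Its median changed sign without WT air replicate 1 (-0.022), without WT air replicate 2 (-0.017) and with the 8 like arrays (-0.004), and its camera direction was up in the 8-array replicate block (adjusted p = 0.891). In HRE2ox against WT under hypoxia, no filter brought a call (median -0.11, adjusted p = 0.0204). Signal over background limits dim probe sets, and 9059 of 22746 were left out.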

Other observations

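The tests in this part, on added controls, GAPDH and 2 probe sets without an assigned gene, were all chosen only after the result was seen.

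Genes differed between replicate 1 and replicate 2 within WT and HRE1ox, fitted over 8 arrays. Chloroplast-encoded atpF, of the ATP synthase, and rbcL, the large Rubisco subunit, were higher in replicate 1 by 2.14 ± 0.07 and 2.10 ± 0.13, and the ribosomal protein rpl14 by 1.79 ± 0.09, while psbN was lower, at -2.26 ± 0.09. The expansin EXPA4 was higher by 1.47 ± 0.09. In all 2826 probe sets were higher and 2472 lower by limma, and the first within-group component held 68.9% of the variance. On a scale where WT replicate 1 stands near 1 and replicate 2 at 0, the HRE1ox arrays stood at 0.98 and -0.01 in air and 0.92 and -0.09 in hypoxia, and the HRE2ox arrays at 0.15 and 0.34 in air and 0.08 and 0.66 in hypoxia.

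RNA labelling that differed between arrays may explain the replicate pattern. The lowest thr 5' control of these 4 arrays stood 3.51 log2 above the highest of the other 8. The 4 were separated at the largest gap of that control, so a gap was certain, but the arrays found are replicate 1 of the WT and HRE1ox groups. The dap 5' control, not used for the split, read 9.33 to 9.58 on them against 4.94 to 6.67. RNA breakdown cannot be told apart from uneven labelling. GAPDH 3' minus 5' signal was larger in replicate 2 by 0.74 log2 in the mean of 4 groups, but the 3' minus 5' signal of the added thr transcript, which did not come from the seedlings, moved too. No biological explanation was tested.

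Probe set 260451_at was at 14.19 and 14.25 in HRE1ox air and hypoxia, a difference of 0.06, while it rose from 6.18 to 10.50 in WT and from 6.71 to 10.39 in HRE2ox. A candidate explanation is that it reads the introduced HRE1 transcript. Probe set 245173_at was at 14.45 and 14.46 in HRE2ox air and hypoxia, a difference of 0.01, while it rose from 3.31 to 9.48 in WT and from 3.16 to 9.50 in HRE1ox. It may likewise read the introduced HRE2 transcript. No probe set was assigned to either gene, so both remain hypotheses from levels alone.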
